A study of Mus musculus with 8 samples.

How the data were processed

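RNA sequencing libraries from 8 samples of mouse kidney cells were analysed. Per the labels, the cells are a line called RFB with the cell type fibroblast, and all 8 samples received TGF-β, a cytokine that drives fibroblasts to make extracellular matrix. In 4 samples TGF-β was the only treatment, and in 4 samples chaetocin was added. Chaetocin is a fungal metabolite used as an inhibitor of the SUV39 family of histone H3 lysine methyltransferases, and it can also act on redox enzymes. Doses and times are not given in the sources used here. Samples were grouped by the treatment label alone, although the design text of the series speaks of knockdown cells, which no label of these samples mentions. Nothing in the labels says that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. No sample without TGF-β was analysed here, so no value describes the effect of TGF-β itself.

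Per the labels' protocols, RNA was extracted with an RNeasy column kit and libraries were made with a SMARTER mRNA kit. Whether the counting used strand is not given in the sources used here, so reads from overlapping genes on opposite strands cannot be told apart. The build was GRCm38, also called mm10, per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here. Per the file headers, the authors deposited 1 table of 22274 genes with a whole-number read count and an FPKM value for each gene and sample. The counts as deposited are not normalized. FPKM values are by definition divided by gene length and by depth. The deposited ones differ from the counts by more than 1 common shift of scale. Their log2 ratio was -0.74 for Dnmt3a and 1.24 for Birc2, where the main test described below gave -1.14 and 1.27. Fits on FPKM therefore differ from fits on counts by more than scaling. The same table holds the authors' mean FPKM of each group, the authors' log2 ratio of these means, and the authors' p-value and FDR from a test that the table does not name. The authors' columns were used for a comparison of signs, and 0 columns of other samples were present.

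The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr, TMM scaling and no fold minimum. It kept 14608 genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 counted as a call. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are given as TMM-scaled CPM, counts scaled to a common library size, with the SD over the 4 libraries of a group. Gene lists were tested with camera in limma 3.58.1, with an inter-gene correlation preset at 0.01 and adjustment over all lists with at least 5 tested members. All adjusted p-values of single genes below come from edgeR and those of lists from camera, both after Benjamini-Hochberg adjustment, unless another tool is named. Exact two-sided permutation tests on log2 CPM were added for the genes in the title of the series and for values per library. With 4 libraries against 4 the smallest p these tests can give is 0.0286.

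The 25 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Cxcl10, Suv39h1 and Suv39h2 in every case. It adds the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, whose mean log2 CPM is at least 3 and whose symbol is not a predicted or clone name. It also adds, for each list, the 2 called members with the smallest p in each direction, or the 2 smallest p where no member was called. It gave 107 genes, of which a few are not reported here by name. Genes named outside it are said to have been chosen after their values were seen. Pathways of the deposited KEGG annotation with 10 to 300 tested genes were tested with camera as a further description.

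The alternatives were DESeq2 size factors, total-count scaling, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) of genes with FPKM above 1 in at least 4 samples, a pseudocount of 0.1, no FPKM filter, a replicate block, mitochondrial transcripts left out, each library left out, a fold of at least 2, glmTreat against a fold of 1.5, camera with an estimated correlation, and fry. Counts were simulated with the mean levels of the TGF-β libraries and the dispersions and library sizes of this comparison, and 13140 genes were tested. The test recovered 92% of 50 genes set to a log2 fold of -1, 86% at -0.5, 84% at 0.5 and 100% at 1. Of 12940 genes simulated without a change, 16 were called. The simulated changes were few, balanced between rises and falls, and set only in genes with enough expected counts. In the real comparison most genes were called, so these rates check the test and do not give the error rate of its calls here. Python 3.11.15 with SciPy 1.17.1 was used for the remaining tests.

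Gene positions are those of the GENCODE mouse release M21 annotation on GRCm38, matched by gene ID for 22219 of the 22274 genes. Exon overlaps were searched among protein-coding genes and the main classes of long non-coding RNA. The count at or under which a gene was treated as silent was 3 over the 4 libraries of a group. A fold against a group at 0 counts was computed against a floor of 3 counts over the group and is a lower bound. Folds against 1 to 3 counts carry an exact 95% Clopper-Pearson counting interval. Intervals and floors cover counting error only, since reads are not independent molecules.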

Results

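The data were gene-level read counts from 8 RNA sequencing libraries of RFB mouse kidney cells, 4 treated with TGF-β alone and 4 with TGF-β and chaetocin. Total counts were 20135312 to 23664084 in the TGF-β libraries. With chaetocin they were 22591935 in replicate 1 and 14421225 to 15084876 in the other 3. A count of 3 corresponded to 0.127 to 0.208 CPM, depending on the library. Replicates differed by more than sampling noise in every pair, with a mean chi-square per gene of 2.05 to 2.65. Such an excess does not show whether the libraries came from separate cultures. Each library was counted as 1 replicate. The series title names Suv39h1 as a target in renal fibrosis and the transcription of CXCL10, a chemokine that attracts T cells. The comparison asked how the transcriptome of TGF-β-treated cells differed when the inhibitor was present.

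Cxcl10 was higher with chaetocin in all 4 libraries, at 37.7 ± 3.63 CPM (SD, n = 4) against 10.3 ± 1.95 CPM with TGF-β alone. The log2 fold change was 1.86 ± 0.09 (SE), with an edgeR Benjamini-Hochberg adjusted p of 4.8e-17. In an exact two-sided permutation test on log2 CPM the difference gave p = 0.0286, the smallest that 4 against 4 libraries allow. The counts behind these values were 174 to 257 in the TGF-β libraries and 561 to 792 with chaetocin. Cxcl10 (ENSMUSG00000034855) is a protein-coding gene on chromosome 5, positions 92346638 to 92348889, minus strand, and 133 bases of its exons overlap Art3 on the opposite strand.

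Suv39h1, which encodes a methyltransferase for lysine 9 of histone H3, was slightly lower with chaetocin, at 24.7 ± 1.94 CPM against 28.7 ± 0.741 CPM (SD, n = 4 per group). Its log2 fold change was -0.21 ± 0.06 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00154), and the exact permutation p was 0.0286. Under total-count scaling the log2 fold change was -0.09 and was not called (edgeR adjusted p = 0.126). Its paralog Suv39h2 was higher, at 5.70 ± 0.403 CPM against 3.88 ± 0.567 CPM (log2 fold change 0.55 ± 0.13 SE; edgeR adjusted p = 4.8e-04). Chaetocin acts on the enzymes, so transcript levels do not check the treatment labels. The series' design text speaks of Suv39h1 knockdown cells, which the labels of these 8 libraries do not mention, and whether a knockdown is part of either group stays open. Suv39h1 (ENSMUSG00000039231) lies on chromosome X, positions 8061171 to 8074760, minus strand, and 767 exon bases overlap Gm14820 on the opposite strand. Suv39h2 (ENSMUSG00000026646) lies on chromosome 2, positions 3455815 to 3475031, minus strand, and its exons overlap Dclre1c and Gm13184 on the opposite strand.

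**Figure D1:**
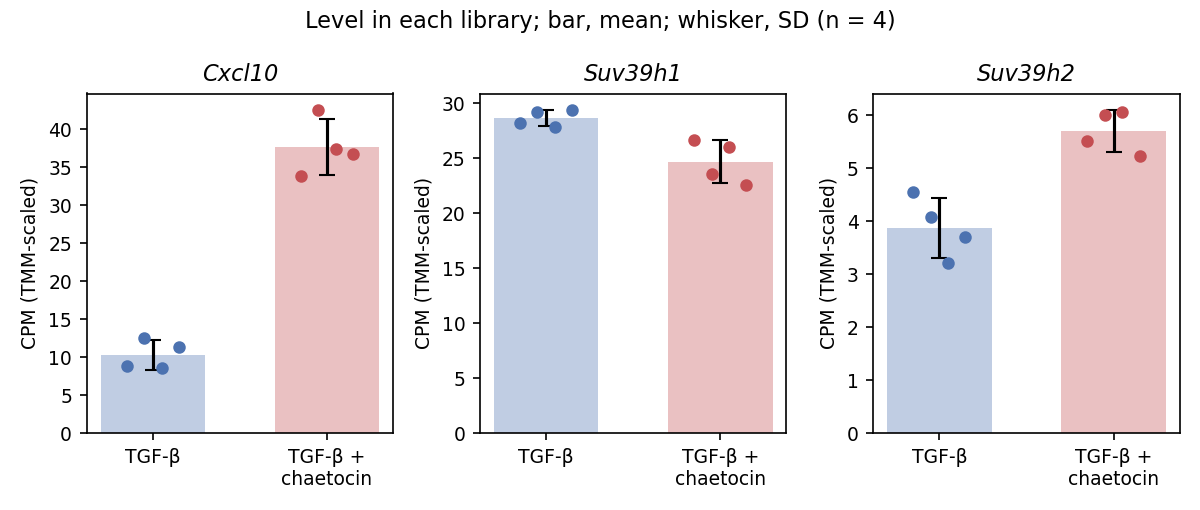
TMM-scaled CPM (y axis) of Cxcl10, Suv39h1 and Suv39h2 in each library, by treatment (x axis); points are libraries, bars the mean of 4 and whiskers the SD. Cxcl10 lay between 33.8 and 42.6 CPM with chaetocin and between 8.59 and 12.6 CPM with TGF-β alone.

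Chaetocin was accompanied by a change in most tested genes. Of 14608 genes tested, 6129 were higher and 5662 lower with chaetocin (edgeR, Benjamini-Hochberg), 80.7% of those tested. The spread between replicates was small, so small changes could also be called. The common biological coefficient of variation, the edgeR estimate of spread beyond counting noise, was 2.94%. Under total-count scaling 7180 were higher and 4514 lower, so the balance of rises and falls depends on scaling. With a fitted fold of at least 2 the counts were 2884 higher and 713 lower, so larger changes were mostly rises. The groups did not overlap in 10916 genes, 74.7% of those tested, where chance gives 2.86%. The first principal component of log2 CPM held 92.5% of the variance and separated the treatments. Correlations across genes were at least 0.993 between libraries of a group and at most 0.917 between groups. The median log2 fold change of all tested genes was 0.02, and 0.14 under total-count scaling. Because of that shift the direction of small changes can depend on scaling. Of the 11791 genes called, 10643 were also called with the same sign under total-count scaling and 9 with the opposite sign. That 0 of the 107 named genes changed sign says little, since most were named for a large fold or a small p.

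Among called genes with a mean log2 CPM of at least 3, the largest rises were in genes with almost no counts under TGF-β alone. Dntt, the template-independent DNA polymerase of lymphocyte precursors, had 0 counts in each TGF-β library and 913 to 1588 counts with chaetocin, at least 1789-fold higher. Pla2g4e, a cytosolic phospholipase A2, also had 0 counts and rose at least 574-fold. The immediate early transcription factor Egr4 had 2 counts over the TGF-β libraries and 1406 with chaetocin, a ratio of 848 with a counting interval of 234 to 7012. Fer1l6, the axonemal dynein heavy chains Dnah12 and Dnah11, the protease inhibitor Serpinb2, the epithelial transcription factor Ovol1, the germ cell gene Tex14 and the epidermal lipoxygenase Aloxe3 completed the 10 largest rises above that level, each below 0.25 CPM without chaetocin. Of these, Serpinb2 reached 28.6 ± 1.83 CPM (SD, n = 4). The exons of Dnah11 overlap Cdca7l on the opposite strand, so its counts are less certain. The same holds for 21 of the 107 named genes in all, since strand is unknown. Dntt (ENSMUSG00000025014) lies on chromosome 19, positions 41029275 to 41059525, plus strand.

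The largest falls were taken at the same minimum level. Igfbp5, an insulin-like growth factor binding protein, fell from 18.2 ± 0.406 to 0.725 ± 0.328 CPM (SD, n = 4 per group; log2 fold change -4.68 ± 0.15 SE; edgeR adjusted p = 5.1e-21). Grem1, a secreted antagonist of bone morphogenetic proteins, fell from 144.2 ± 4.89 to 10.9 ± 2.48 CPM (log2 fold change -3.76). Mmp9, a gelatinase, fell from 278.8 ± 22.3 to 30.1 ± 2.83 CPM (log2 fold change -3.22). Lrig3, C1qtnf3, Cyp1b1, Adgra1, the ligand gene Wnt10b, the cortisol-inactivating enzyme gene Hsd11b2 and Kif26b fell by 2.77 to 3.32 on the log2 scale. Igfbp5 lies on chromosome 1, positions 72857932 to 72874884, minus strand, and Grem1 on chromosome 2, positions 113746164 to 113758646, minus strand.

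**Figure D2:**
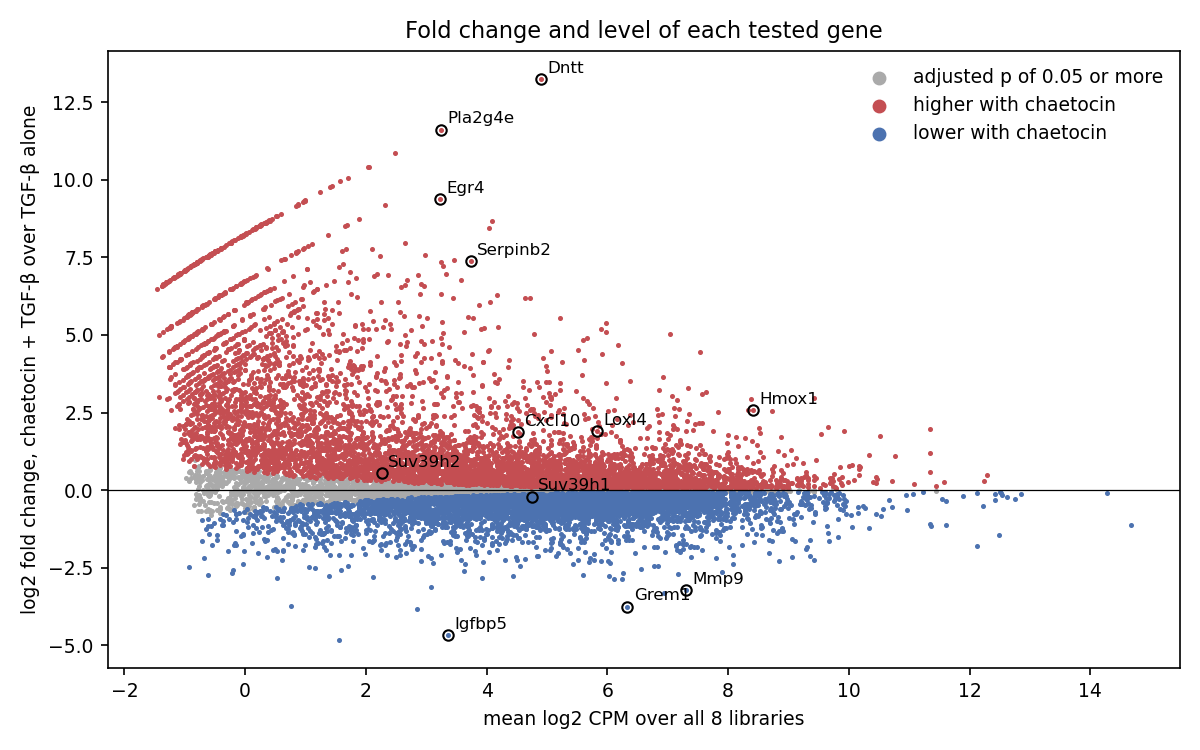
Log2 fold change with chaetocin (y axis) against mean log2 CPM over the 8 libraries (x axis) for the 14608 tested genes; red points were higher, blue points lower and grey points not called, and circles mark named genes. Large rises lie mostly at low mean levels, and the stripes at the upper left are genes with few counts under TGF-β alone.

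Matrix and myofibroblast genes were mostly lower with chaetocin. Of 40 tested members, 30 fell and 6 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.89. Thbs1, a matrix glycoprotein that activates latent TGF-β, fell from 8358 ± 111 to 3092 ± 97.0 CPM (SD, n = 4 per group), and the metalloprotease gene Adam12 from 798.1 ± 10.6 to 268 ± 10.8 CPM. Col1a1, chosen after its values were seen, fell by 2.01 on the log2 scale. In contrast Acta2, the smooth muscle actin used as a myofibroblast marker, rose from 1248 ± 16.8 to 1598 ± 86.9 CPM (log2 fold change 0.36 ± 0.03 SE; edgeR adjusted p = 1.9e-12), and the collagen cross-linking enzyme gene Loxl4 rose by 1.91 on the log2 scale. The list was lower by camera (Benjamini-Hochberg adjusted p = 2.9e-16). That call was lost at adjusted p = 0.0679 with an estimated correlation.

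Components and feedback genes of the TGF-β pathway fell in 22 of 26 tested cases and rose in 3, also adjusted over the list alone. The median was -0.67 on the log2 scale (camera adjusted p = 5.6e-09; adjusted p = 0.0195 with an estimated correlation). Ltbp2, a latent TGF-β binding protein, had a log2 fold change of -1.85 and Pmepa1, a feedback inhibitor, one of -1.11. Id2 and Id3, targets of bone morphogenetic protein signalling, rose by 1.95 and 0.68. Id1 and Smad6, which are also such targets and were chosen after their values were seen, fell by 1.10 and 0.75. Proteases and their inhibitors fell in 18 of 28 cases and rose in 7, also adjusted over the list alone (median -0.57; camera adjusted p = 1.3e-07; adjusted p = 0.0394 with an estimated correlation). Among them Adamts1 had a log2 fold change of -2.10, whereas Plaur, the urokinase receptor, rose by 1.66.

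All 45 tested interferon-stimulated genes rose, over all genes and adjusted over the list alone, with a median log2 fold change of 2.99. Ifit3 rose from 16.6 ± 4.20 to 362.2 ± 27.3 CPM and Ifit3b from 5.69 ± 1.85 to 145.3 ± 9.65 CPM (SD, n = 4 per group). These antiviral effectors are close paralogs whose reads may be shared. The list was higher by camera (adjusted p = 3.4e-53; adjusted p = 0.0455 with an estimated correlation). Chemokines and interleukins went both ways, with 13 of 28 higher and 11 lower, also adjusted over the list alone, and no call as a list (median 0.61; camera adjusted p = 0.972). Under total-count scaling 14 rose and 8 fell. Beside Cxcl10, the interleukin 1 receptor antagonist Il1rn rose by 2.43 on the log2 scale, and Il11, a profibrotic cytokine gene, had a log2 fold change of -2.27 and Csf1 one of -1.22. NF-kB targets were divided too, with 8 higher and 9 lower of 23, also adjusted over the list alone (median 0.00; camera adjusted p = 0.610). Their mean was 0.04 while camera gave the direction down, and under total-count scaling 11 rose and 9 fell, with a median of 0.11. Tnfaip2 rose by 1.90 and Birc2 by 1.27, while Cd44 had a log2 fold change of -1.21 and Tnfaip3 one of -1.05.

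Antioxidant genes controlled by NRF2 rose in 27 of 30 cases and fell in 1, also adjusted over the list alone (median 1.10; camera adjusted p = 5.8e-24; adjusted p = 0.00271 with an estimated correlation). Hmox1, which encodes a heme-degrading enzyme, rose from 99.1 ± 3.43 to 587.7 ± 22.5 CPM and the sulfiredoxin gene Srxn1 from 41.1 ± 2.68 to 365.1 ± 14.6 CPM (SD, n = 4 per group). Aifm2 was the member that fell, by 0.42 on the log2 scale. Cytosolic heat shock genes rose in 17 of 24 cases and fell in 5, also adjusted over the list alone (median 0.50; camera adjusted p = 6.3e-08; adjusted p = 0.0219 with an estimated correlation). Hsp90aa1 reached 4166 ± 139 CPM from 1057 ± 27.2 CPM, and Hspa1a, a near-identical paralog of Hspa1b, rose by 2.86 on the log2 scale. The collagen chaperone gene Serpinh1 had a log2 fold change of -0.45 and Fkbp4 one of -0.29.

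Chaperones of the endoplasmic reticulum fell in 20 of 24 cases and rose in 2, also adjusted over the list alone, with Hspa5 at a log2 fold change of -0.60 and Pdia4 at -0.75. Atf6 and Creld2 rose by 0.41 and 0.37. The list had a median of -0.37 (camera adjusted p = 1.4e-04), and the call was lost at adjusted p = 0.217 with an estimated correlation. Metallothionein and metal response genes rose in 6 of 7 cases and fell in 1, also adjusted over the list alone, with Mt1 up by 0.94, Mt2 by 0.88 and the zinc exporter gene Slc30a1 at -0.71. Their median was 0.75 (camera adjusted p = 0.0157), and the call was lost at adjusted p = 0.112 with an estimated correlation and at adjusted p = 0.141 to 0.167 with limma on FPKM. Genes of the ATF4 stress response were higher in 13 and lower in 13 of 29 cases, also adjusted over the list alone (median -0.02; camera adjusted p = 0.371). Under total-count scaling 16 rose and 13 fell, with a median of 0.10. Atf3 rose by 1.46 and Slc3a2 from 185.4 ± 6.48 to 371 ± 4.82 CPM (SD, n = 4 per group), and Nupr1 had a log2 fold change of -2.01 and Vldlr one of -1.25.

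All 32 tested mitosis genes and all 34 tested genes of DNA replication and S phase rose, over all genes and adjusted over each list alone. The mitosis genes had a median log2 fold change of 0.83, with Anln, a cytokinesis gene, at 1.10 and the spindle factor Tpx2 at 0.78 (camera adjusted p = 4.1e-05). That call was lost at adjusted p = 0.114 with an estimated correlation. The S phase genes had a median of 0.73, with the replication licensing factor Cdt1 at 2.54 and the cyclin gene Ccne2 at 2.68 (camera adjusted p = 1.4e-06; adjusted p = 0.0195 with an estimated correlation). Targets of p53 rose in 8 and fell in 16 of 29 cases, also adjusted over the list alone (median -0.11; camera adjusted p = 0.307). Under total-count scaling 11 rose and 9 fell, with a median of 0.00. Gdf15 rose by 1.26 and Bax by 0.75, and Pmaip1 had a log2 fold change of -1.31 and Phlda3 one of -0.84.

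Immediate early genes rose in 17 and fell in 10 of 29 cases, also adjusted over the list alone, with Egr1 up by 2.57, Klf10 by 2.46, Myc at -0.99 and Ier5 at -0.77. The median was 0.47 (camera adjusted p = 0.00117), and the call was lost at adjusted p = 0.245 with an estimated correlation. It was also lost with limma-voom (adjusted p = 0.0771) and with limma on FPKM (adjusted p = 0.115 to 0.172). Germline genes that are normally silent in somatic cells rose in 16 of 19 tested cases, also adjusted over the list alone. The list has 40 members, and only those with enough counts in 4 libraries could be tested, which favours genes that rose. Their median log2 fold change was 3.58, and 3.58 with the 2 members at 0 counts taken at their bound. Tex14 and the piRNA pathway helicase gene Mov10l1 rose by 6.96 and 5.32 (camera adjusted p = 0.00672). The call was lost at adjusted p = 0.212 with an estimated correlation. Tex14 belongs to both this list and the largest rises.

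The machinery of histone H3 lysine 9 methylation and heterochromatin rose in 13 and fell in 22 of 37 cases, also adjusted over the list alone, with no call as a list (median -0.23, and -0.11 under total-count scaling; camera adjusted p = 0.319). The histone chaperone gene Daxx rose by 2.09 and the heterochromatin protein gene Cbx5 by 0.57. Dnmt3a and Atrx had log2 fold changes of -1.14 and -0.70. Cholesterol synthesis genes rose in 5 and fell in 15 of 25 cases, also adjusted over the list alone (median -0.21; camera adjusted p = 0.308), with Idi1, an isomerase gene of the pathway, at 0.39. Under total-count scaling 9 rose and 13 fell, with a median of -0.09. Glycolysis and hypoxia genes rose in 15 and fell in 13 of 29 cases, also adjusted over the list alone (median 0.08, and 0.20 under total-count scaling; camera adjusted p = 0.936), with Adm at 3.32, Pkm at 0.49, Hk2 at -0.70 and Vegfa at -0.76. Of 13 mitochondrially encoded transcripts 10 fell, also adjusted over the list alone, among them mt-Cytb at -0.28 and mt-Nd5 at -0.32 (median -0.10; camera adjusted p = 0.226). With limma-voom the list was called lower (adjusted p = 0.0113). Under total-count scaling 4 fell and 2 rose, with a median of 0.01.

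**Figure D3:**
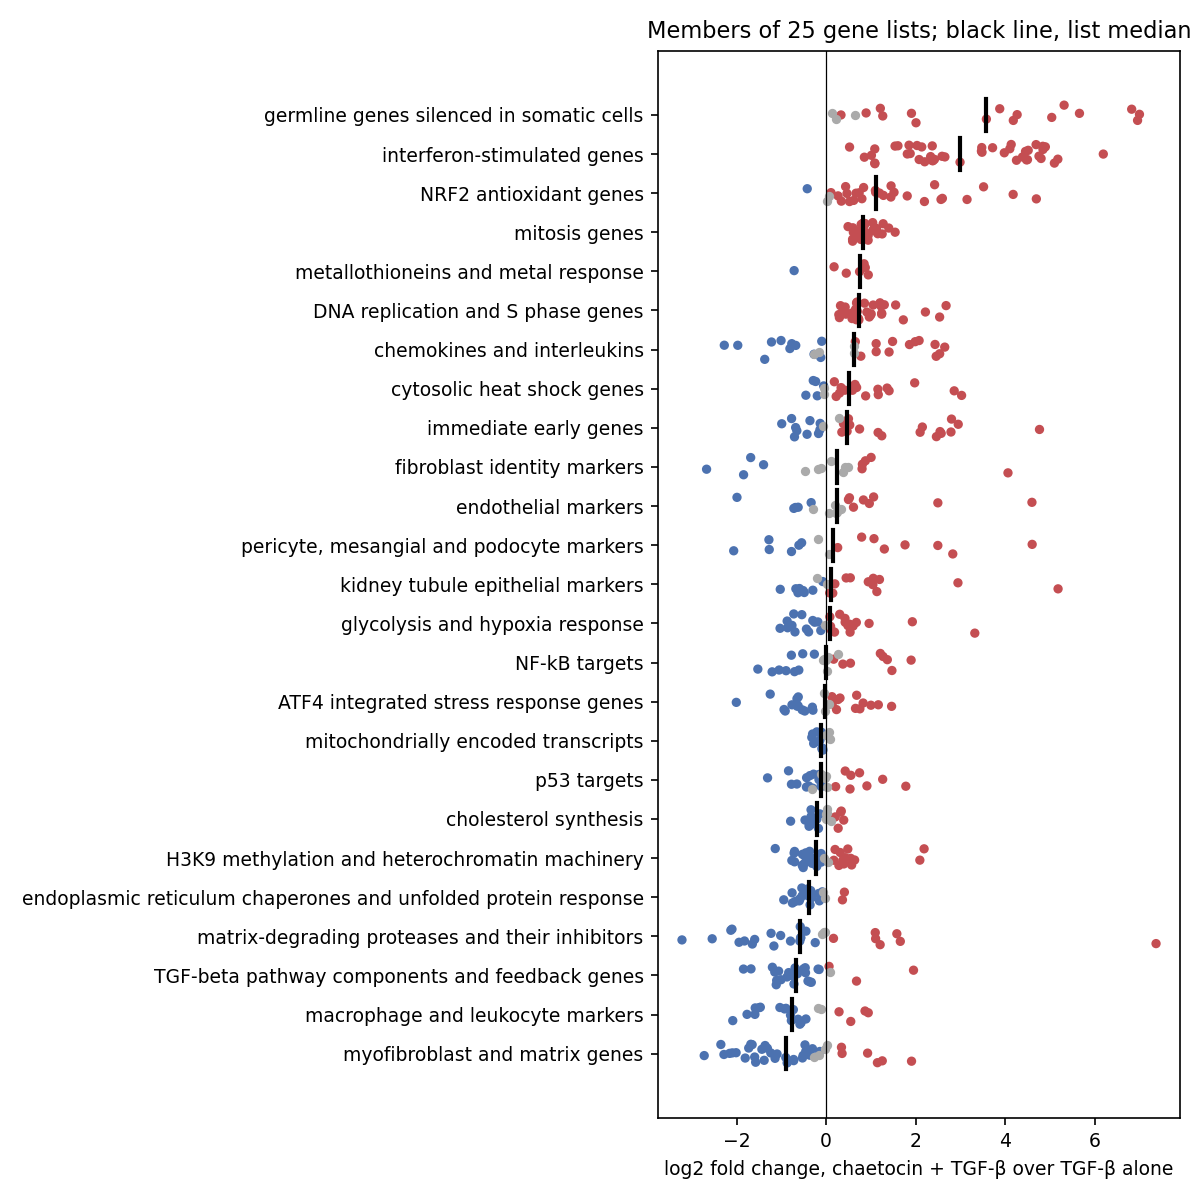
Log2 fold change with chaetocin (x axis) of each tested member of the 25 gene lists (y axis, ordered by median); red points were higher, blue points lower and grey points not called, and the black line is the list median. All 45 interferon-stimulated genes lie to the right of 0, and 30 of 40 matrix genes are called to the left.

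Markers of other cell types were measured in the same libraries. Epithelial keratins were abundant, with Krt8 at 1582 ± 29.6 CPM under TGF-β alone and 3615 ± 46.6 CPM with chaetocin, and Krt18 at 812.4 ± 18.4 and 1783 ± 43.4 CPM (SD, n = 4 per group). Among tubule epithelial markers 12 of 22 rose and 8 fell, also adjusted over the list alone, with Cldn4 at -0.51 on the log2 scale (median 0.11, and 0.23 under total-count scaling; camera adjusted p = 0.0123). That call was lost at adjusted p = 0.285 with an estimated correlation, at adjusted p = 0.250 with limma-voom and at adjusted p = 0.257 to 0.436 with limma on FPKM. Macrophage and leukocyte markers fell in 16 of 22 cases and rose in 4, also adjusted over the list alone, with C1qc at -1.77, Cx3cr1 at -2.09, Cd68 at 0.94 and Cd14 at 0.87. Their median was -0.75 (camera adjusted p = 0.00707), and the call was lost at adjusted p = 0.450 with an estimated correlation. These markers moved in the libraries in which interferon-stimulated genes rose and matrix genes fell.

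Fibroblast identity markers rose in 5 and fell in 4 of 16 tested cases, and 4 rose and 4 fell adjusted over the list alone. Ly6a rose by 1.01 and Dcn by 4.06, the latter from 0.129 ± 0.0556 CPM (SD, n = 4), while Fbln2 had a log2 fold change of -1.84 and Nt5e one of -2.67. The median of 0.25 and the mean of 0.04 were above 0, whereas camera gave the direction down without a call (adjusted p = 0.0709). The list was called lower under total-count scaling (camera adjusted p = 0.0401), with a replicate block (camera adjusted p = 0.0369) and without chaetocin replicate 3 (camera adjusted p = 0.0179). Camera compares a list with the other genes, and under total-count scaling 6 members rose and 4 fell, with a median of 0.37. With an estimated correlation there was no call (camera adjusted p = 0.201). Endothelial markers rose in 8 and fell in 5 of 19 cases, also adjusted over the list alone (median 0.25; camera adjusted p = 0.365), with Vwf at 4.60, Kdr at 2.50, Ptprb at -1.99 and Emcn at -0.62. Pericyte, mesangial and podocyte markers rose in 8 and fell in 6 of 16 cases, and 8 rose and 7 fell adjusted over the list alone. Their median was 0.16, or 0.27 under total-count scaling, and their mean 0.53, and camera again gave the direction down without a call (adjusted p = 0.226). Abcc9 and Clic5 had log2 fold changes of 4.60 and 2.83, and Mcam and Pdgfb of -1.28 and -0.77.

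The authors' deposited table gave an FDR under 0.05 to 7608 genes higher and 5043 lower with chaetocin. Of the 11791 genes called here, 10842 passed in the authors' deposited table with the same sign and 286 with the opposite sign. For Cxcl10 the authors' deposited table gave a log2 ratio of 1.98 and for Suv39h1 one of -0.10.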

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

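The tests of uniform background, of leukocyte share, of interferon transcripts and of fibroblast share were chosen after the results they measure had been seen. The tests of scaling, read-through and other groupings were written before.

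The depth of chaetocin replicate 1 stood apart, at 22591935 counts against 15084876 in the next deepest library of its group, and it also had the most genes with a count, 18454 against a median of 18002. In 9 further groups of 4 libraries 1 library lay far from the other 3 in log2 CPM. With TGF-β alone these were Il1rn at 3.72, Aifm2 at 4.14, Serpinh1 at 9.36, Anln at 4.99, Cdt1 at 2.96 and C1qc at 5.68. With chaetocin they were Lrig3 at 4.34, Anln at 5.91 and Pmaip1 at 8.10. In all, 11 of 216 groups tested stood out this way, where chance gives about 10.8.

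Of 35 ways to divide the 8 libraries into 4 and 4, only 1, the treatment itself, gave as many as 11791 called genes, and the highest count of the others was 0. This argues against a chance division as the source of that count, but only at 1 of 35, the least such a test can give. Every other division mixes treated and untreated libraries, so its 0 calls do not measure what chance alone gives. The test cannot separate the treatment from any other difference between the groups.

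Among 6692 genes with at most 3 counts over the TGF-β libraries, 404 were called higher with chaetocin, with a median of 87.5 counts over 4 libraries. The reverse was rare: 1 gene silent with chaetocin had 40 counts or more over the TGF-β libraries, against 513 genes the other way. A uniform background such as genomic DNA as the source of all these counts is argued against. Of silent genes with at least 1 kb of exon, 53.3% stayed at 3 counts or fewer, where 1.91% would stay at the mean rate. That mean includes the induced genes themselves, and 53.3% lies close to the 50% line set for this test. A weaker uniform background at the rate of the median silent gene would give 0.0219% of the 482 silent genes that reached the lowest called count. So low a share follows from the rate itself, which was set at the median of these genes, 1.13 counts per kb of exon, while the lowest called count was 40. So weak a background may be present, since these tests cannot exclude it, but it would not bring genes to that count. The search for read-through covered same-strand genes that rose at least 2-fold and end within 20 kb upstream. Such a neighbour was found for 8.66% of the 404 genes, against 3.93% of silent genes not called (Fisher's exact test, p = 5.2e-05). Read-through of this kind could account for a small part and not for most. Read-through over longer distances or from the opposite strand was not tested. A background that is uneven along the genome was not tested, and the effect of chaetocin on silenced genes remains a hypothesis.

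The rise of interferon-stimulated genes kept a median of 3.11 under total-count scaling, so the choice between TMM and total counts does not account for it. Both scalings are relative, and a change in total RNA per cell cannot be seen with either. More leukocytes would raise the other macrophage and leukocyte markers, but 19 of them, leaving out Cd74, H2-Ab1 and Ctss, had a median log2 change of -0.78. Interferon transcripts could be a source in the same libraries: the summed counts of 21 interferon genes were 229 over the chaetocin libraries and 36 over the others. Most of these counts came from Ifnz, which was also present without chaetocin, so the test that required none there was not met and the question stays open. Ifnab, chosen after its values were seen, had 8 to 14 counts with chaetocin and 0 in each TGF-β library.

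The fall of matrix genes kept a median of -0.77 under total-count scaling, so the choice between TMM and total counts does not account for it. Here too a change in total RNA per cell cannot be seen with either scaling. A lower share of fibroblasts may contribute and cannot be told apart from a change within cells: of the fibroblast identity markers with a mean log2 CPM of at least 3, 2 were called higher (Cd34 and Ly6a) and 4 lower (Pdgfrb, Vim, Fbln2 and Nt5e). The abundance minimum was added after these values were seen, because markers near the floor exclude nothing. Without it 5 rose and 4 fell, which would have counted against a lower share. Unlike in the leukocyte test, no marker was left out here as one that interferon might induce. Epithelial genes were abundant in the same libraries, so which cells made the matrix transcripts is not known. A change within the cells in response to chaetocin was not tested separately.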

How the results depend on the processing

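All alternatives but 1, thinning, were chosen before the data were examined. Cxcl10 stayed called in every fit run for single genes, which leaves out the fold minimum and glmTreat, with log2 fold changes from 1.78 to 1.98. Suv39h1 kept its sign but lost its call under total-count scaling (-0.095, adjusted p = 0.126), and with limma on log2(FPKM + 1) (-0.094, adjusted p = 0.135), on log2(FPKM + 0.1) (-0.10, adjusted p = 0.134) and on log2(FPKM + 1) without a filter (-0.094, adjusted p = 0.143). For Suv39h1 the FPKM fits lay close to the value under total-count scaling, so these 4 are not separate evidence. Over its other alternatives its adjusted p ranged up to 0.00929, without chaetocin replicate 4.

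Of 6129 genes higher and 5662 lower, 2884 and 713 had a fold of at least 2, and glmTreat against a fold of 1.5 called 3357 and 1492, as stricter thresholds must. The balance of the 2 directions moved with scaling, tool and filter, to 7180 and 4514 under total-count scaling, 7390 and 5360 with DESeq2, 7932 and 6065 without a filter on counts, 5408 and 3973 with limma on log2(FPKM + 1), and 8623 and 4068 when that fit had no filter. Leaving out 1 library gave 6030 to 6276 higher and 5538 to 5677 lower. Of 9 lists higher and 5 lower, 4 and 2 were called by camera with an estimated correlation, and fry, which does not compare a list with other genes, called 11 and 13. Among other results, named genes gave 1987 calls on the same side and 2 weaker, both of Aifm2 with limma on FPKM. Most of these genes were named for a large fold or a small p, which favours stable calls. Lists gave 466 on the same side, 14 now past the threshold and 19 no longer past it. The immediate early and tubule lists were lost with limma-voom, and these 2 and the metallothionein list with all limma fits on FPKM. The fibroblast identity list became a call under total-count scaling and without chaetocin replicate 3, and the mitochondrial list with limma-voom. Same-numbered libraries did not deviate together (correlations of -0.01 to 0.03, with 1 of 8 libraries closest to its own number), and a replicate block called 6105 genes higher and 5643 lower, and the fibroblast identity list lower (camera adjusted p = 0.0369). Depth limits the genes with few counts, where a count of 3 was up to 0.208 CPM.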

Other observations

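The gene families and the pathway test here were chosen after the data were examined, and that of the X chromosome was written before.

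Called genes were also counted by family, without a test of the family as a whole, and some members belong to the fixed lists too. Of 15 axonemal dynein heavy chain genes, the motors of cilia, 13 rose and 1 fell, with a median log2 fold change of 4.26. Clade B serpins, intracellular protease inhibitors, rose in 14 of 15 tested cases (median 3.57), out of 28 in the table, and glutathione S-transferases in 12 of 16 (median 1.17). Schlafen genes rose in 7 of 8 cases and guanylate-binding protein genes in 8 of 9. Histone genes of the H1 and cluster-named core families rose in 31 of 37 tested cases and fell in 5 (median 2.18), out of 69 in the table. Other families went both ways, such as cytochromes P450, with 16 of 31 higher and 6 lower, and genes named Zfp, with 95 of 341 higher and 157 lower (median -0.14). Olfactory receptors, which detect odours in the nose, rose in 56 of the 57 tested, out of 1195 in the table, and vomeronasal receptors in 14 of 15 tested, out of 355. The receptor and histone families hold near-identical copies whose reads can be shared. In every family only members with enough counts in 4 libraries could be tested, which favours genes that rose from near 0. By gene annotation deposited with the counts, 14 of 325 KEGG pathways were higher and 15 lower (camera, Benjamini-Hochberg), with a smallest adjusted p = 0.185 with an estimated correlation. The smallest camera adjusted p was that of olfactory transduction, which was higher, with 71 of 89 genes up and 12 down (adjusted p = 1.6e-04). ECM-receptor interaction was lower, with 27 up and 39 down (camera adjusted p = 2.3e-04). TGF-β signalling was lower too, with 21 up and 54 down (camera adjusted p = 0.0013). Drug metabolism by cytochrome P450 was also among the higher pathways, with 32 of 41 genes up and 2 down (adjusted p = 0.00425; adjusted p = 0.185 with an estimated correlation). Its name does not mean that the P450 genes rose as a family, since those went both ways.

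More genes had at least 1 count with chaetocin, 18096 ± 242 (SD, n = 4) against 15706 ± 106, although depth was lower. Thinned to the smallest library, an alternative chosen after seeing the data, the values were 17973 ± 49.4 and 15390 ± 89.3 (exact permutation p = 0.0286). The share of counts in the 10 most abundant genes was 8.60% ± 0.0685 with chaetocin and 10.8% ± 0.0267 without (exact permutation p = 0.0286, n = 4 per group). The mitochondrial share was 6.67% ± 0.0208 and 6.85% ± 0.165 (exact permutation p = 0.114), and that of ribosomal protein genes 2.61% ± 0.0370 and 2.16% ± 0.0448 (exact permutation p = 0.0286).

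One hypothesis was that silent genes switched on with chaetocin would lie on the X chromosome more often than silent genes that were not called. Of the 404 genes 3.22% lay there, against 6.25% of the others, an odds ratio of 0.499 with an interval of 0.261 to 0.873 (Fisher's exact test, p = 0.0128), so the data argue against it. Fisher's exact tests over 21 chromosomes gave, after Benjamini-Hochberg adjustment, an adjusted p = 0.0538 for the X chromosome, chromosome 5 an odds ratio of 2.14 (adjusted p = 0.00262) and chromosome 1 one of 1.82 (adjusted p = 0.0323). The odds ratio was 0.581 (adjusted p = 0.0175) for chromosome 7, where many olfactory receptor genes lie, and 0.0916 (adjusted p = 0.00762) for the Y chromosome. The value for the Y chromosome rests on 1 gene called and 165 silent genes not called. Whether these cells carry a Y chromosome was not tested, and its absence would also give a low value. Neighbouring genes are not independent.

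Several epithelial and macrophage genes were well above the floor in cells labelled fibroblast, chosen after their values were seen. Cdh1 was at 650.5 ± 8.10 CPM and Epcam at 285.3 ± 7.44 CPM under TGF-β alone (SD, n = 4). Fibroblast identity markers varied there, and 16 of the 25 on the list had enough counts to be tested. Pdgfra was at 3.52 ± 0.335 CPM and Dcn at 0.129 ± 0.0556 CPM. In contrast Fbln2 was at 982.2 ± 33.6 CPM, Ly6a at 175.5 ± 9.67 CPM and Nt5e at 127.3 ± 2.76 CPM. Csf1r was at 50.1 ± 3.29 CPM and Lyz2 at 75.9 ± 2.66 CPM in the same libraries. No test of the origin of these transcripts was made.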
